A study of Homo sapiens with 4 samples.

How the data were processed

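HDAC2, a class I histone deacetylase, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caco2, an established human colon adenocarcinoma cell line, after infection with an empty vector or with PIM1, a serine/threonine kinase. Per the labels there were 4 libraries: an HDAC2 ChIP and an input from each infection. Chromatin was crosslinked with formaldehyde and libraries were amplified by 15 cycles of PCR and sequenced from paired ends, per the labels' protocols. Each group held 1 library, so no difference between the infections has a replicate check, and no p-value was computed across peaks or genes for the comparison of the infections.

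The analysis started from the authors' deposited peak lists, 1 for each HDAC2 ChIP, on GRCh38. The submitters' processing notes name cutadapt 1.18, Trimmomatic 0.38, FastQC, Bowtie2 2.3.4.1, Picard, MACS2 2.1.2 and ChIPseeker, with no role or order. Whether the inputs served as MACS2 controls is not given in the sources used here, nor are the peak-calling settings. The authors' lists give for each peak its start, end and summit, the fold enrichment at the summit over the caller's local background, and −log10 p and −log10 q at the summit. The score column of the deposited lists was read but not used. Fold enrichment, p and q are the authors' values for each peak; they described, ranked or filtered peaks within a list, and values from both lists were only set side by side. The largest q in either list was 0.0481.

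A MACS2 peak with a fold of (pileup + 1)/(background + 1) and a Poisson p has a single pair of values that fits both. Solving for a whole pileup of fragments gave back the deposited fold and −log10 p to a relative tolerance of 1e-05 for 99.99% of peaks in each list. With a pseudocount of 0, 0% of the first 1000 peaks in each list could be solved. The solver was tested on simulated data, where it returned the exact pileup for 100% of 2000 peaks. The measure of spread used in the closing tests was 0.982 for 600 simulated sites with a common factor. It was 2.83 for sites with their own factors (SD 0.3 on the log2 scale). The simulated sites held more fragments on average than the shared peaks tested, so such factors would show less clearly there. The smallest background in a list stands for the caller's genome-wide level and was 2.00 fragments in the Vector list and 1.93 in the PIM1 list. Divided by the fragment lengths read from the spacing of the backgrounds (234 and 226 bp), it gave the relative number of ChIP fragments. These lengths were searched only close to the width of the narrowest peak in each list. Pileup ratios at shared peaks were divided by the ratio of these smallest backgrounds, 1.04.

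Lists were compared by overlap of at least 1 bp, with bedtools 2.31.1 as a check of the count. Chance overlap was described by 100 circular shifts of the PIM1 peaks along each chromosome. Genes came from the RefSeq table for GRCh38.p14, with 19974 protein-coding genes on the autosomes and X. That table gives gene start and end without strand, exons or sequence, so the planned promoter window was replaced by 1 kb either side of both annotated ends of a protein-coding gene, called gene ends here, after the files were seen. A peak elsewhere was placed in a gene body or between genes by its summit. The ends that carry peaks were checked at 469 genes over 10 kb with a named divergent transcript within 2 kb of an end. In the Vector list 199 ends next to the divergent transcript and 3 opposite ends carried a peak; the numbers were 113 and 1 in the PIM1 list. For lack of sequence or strand, the planned matching of random gene lists on GC content, the search for factor motifs, the exclusion of repeats, exon positions and the window at the 5-prime end were not analysed here.

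Except for those counted by nearest peaks under Other observations, genes named for their peaks follow a rule fixed before the data were examined. It takes the 10 shared, 10 Vector-only and 10 PIM1-only gene-end peaks with the highest fold (for shared peaks the lower of both folds), up to 2 genes per class from each fixed gene list, PIM1 and HDAC2 themselves, and the 3 highest-fold peaks of each list. A further limit on the distance of the summit from the gene end, absent from this rule, was taken out after the results were seen. A gene that this rule picks from a fixed list is not reported here. The 18 gene lists were fixed at the same time, 16 as named genes and 2 by a symbol pattern. They cover Wnt, Notch, goblet and secretory cells, absorptive enterocytes, intestinal stem cells, HDAC co-repressor complexes, PIM kinase related genes, junctions, NF-kB and inflammation, immediate early and stress genes, ribosomal proteins, cell cycle, intestinal transcription factors and growth signals, immune, stromal and endothelial, and neuronal markers, replication-dependent histones, and olfactory receptors. Some genes stand in more than 1 list, among them MYC, CCND1, AXIN2, SOX9 and CDX2. Each list's count of genes with a gene-end peak is given with its percentile among 10000 random lists of the same size drawn from all protein-coding genes, counting ties by 0.5. These percentiles describe the libraries and do not test the infection.

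Shares carry exact (Clopper-Pearson) 95% binomial intervals, pileups exact 95% Poisson intervals, and ratios of counts the exact conditional binomial interval. All intervals cover counting error only, since PCR copies and differences between preparations are outside them. Alternatives set before the data were examined were stricter q or fold limits, autosomes and X alone, merging of peaks within 500 bp, reciprocal overlap of 50%, a distance of 1 kb as shared, equal list length, gene ends of 3 kb and the summit inside the window. A common p minimum and random lists matched on gene length and gene number within 1 Mb (5 bins of each) were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.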

Results

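The data were HDAC2 ChIP-seq peak lists from Caco2 cells infected with vector or with PIM1, with 1 library for each infection. The question set by the labels was where HDAC2 sat on chromatin when PIM1 was introduced. The depth behind the lists, recovered from the peak caller's fold and p, was nearly equal: the Vector to PIM1 ratio of ChIP fragments was 1.00. No comparison below has replicates, and fold enrichment is the authors' value for each peak.

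HDAC2 peaks were fewer in PIM1 cells. The Vector list held 11854 peaks and the PIM1 list 7519, a ratio of 1.58 (95% interval 1.53 to 1.62). They covered 5.37 Mb and 3.08 Mb of the autosomes and X. The ratio was above 1 on each of the 23 chromosomes compared, from 1.27 on chromosome 22 (146 PIM1 peaks, 185 Vector peaks) to 2.04 on chromosome 21 (56 and 114). Strong peaks were fewer as well: 193 Vector peaks and 82 PIM1 peaks had a fold of at least 10, and 574 and 255 had a −log10 q of at least 20. The median fold hardly differed, at 4.52 in the Vector list and 4.57 in the PIM1 list, and the median peak was 382.5 bp wide in the Vector list and 353 bp in the PIM1 list.

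**Figure D1:**
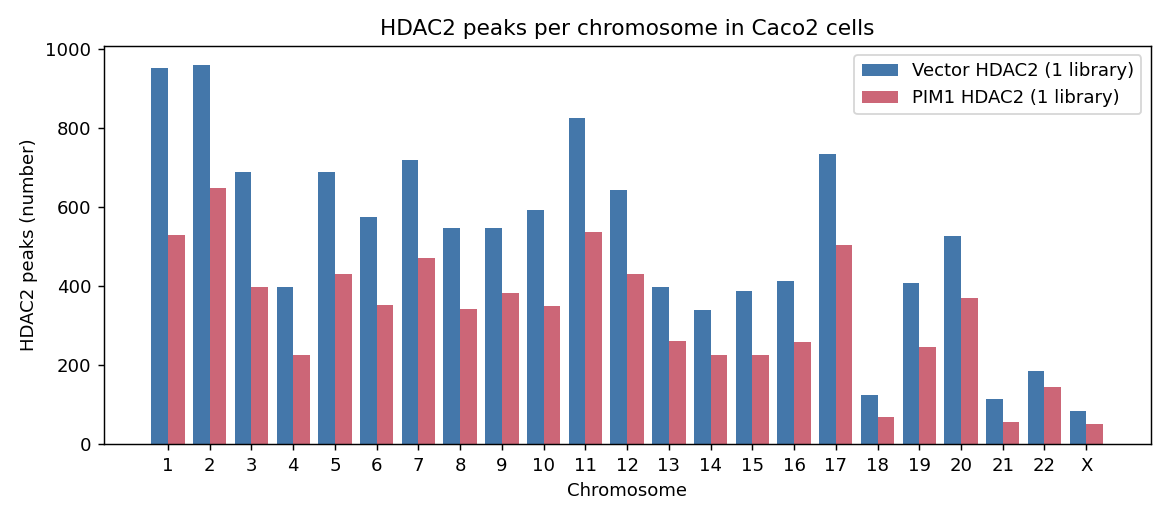
Number of HDAC2 peaks (vertical axis) on each autosome and X (horizontal axis) in the Vector library (blue) and the PIM1 library (red), 1 library each. The Vector bar is the taller on all 23 chromosomes, with ratios from 1.27 to 2.04.

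The highest fold in each list lay at the end of ZEB1, a transcription factor of the epithelial-mesenchymal transition. In Vector cells this peak (chromosome 10, 31319155 to 31320595) had a fold of 45.9 and a pileup of 143 fragments (95% interval 121 to 168); in PIM1 cells (31319142 to 31319851) the fold was 34.0 and the pileup 108 (88.6 to 130). Next in the Vector list came TDRD7, a tudor domain protein (chromosome 9, 97411731 to 97412423, fold 29.0), and PKDCC, a secreted protein kinase (chromosome 2, 42047380 to 42047929, fold 26.5). Next in the PIM1 list came a peak in the body of CAMTA1, a calmodulin-binding transcription activator (chromosome 1, 7704790 to 7705501, fold 27.4), and OVOL1, an epithelial zinc finger factor (chromosome 11, 65786394 to 65787226, fold 19.6).

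Of the Vector peaks 43.6% (42.7 to 44.5; 5166 peaks) were overlapped by a PIM1 peak, and of the PIM1 peaks 69.3% (68.3 to 70.4; 5214 peaks) by a Vector peak. Circular shifts gave a mean of 0.250% and 0.395%. Sharing followed peak strength. In the strongest 20% of the Vector list by p, 80.6% of peaks were shared, and in the weakest 20% 19.2%; in the PIM1 list the shares were 93.4% and 47.0%. Of the 100 strongest peaks, 99 Vector peaks and 100 PIM1 peaks were shared. A shared peak had the higher fold in 68.3% of all pairs of a shared and an unshared Vector peak and in 64.7% of such PIM1 pairs, with median folds of 5.07 and 4.21 in the Vector list and 4.78 and 4.17 in the PIM1 list. Shared peaks were also wider, with medians of 450 and 340 bp in the Vector list and 385 and 302 bp in the PIM1 list.

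**Figure D2:**
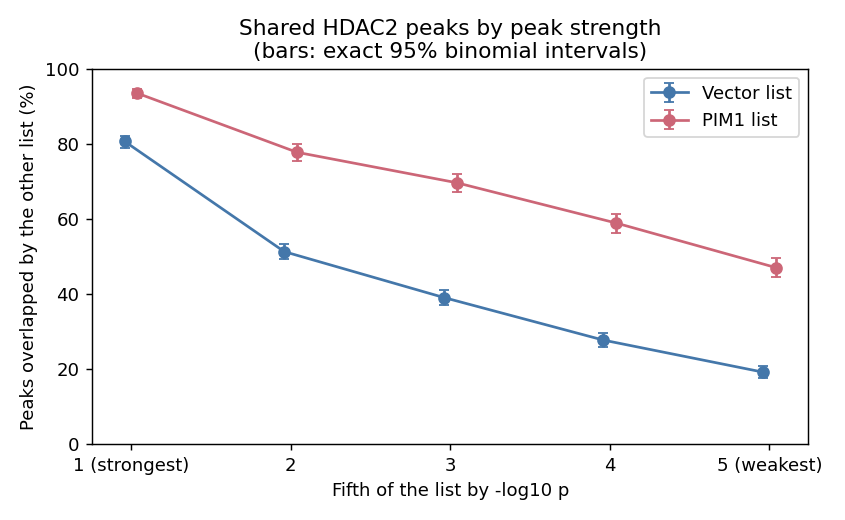
Percent of peaks overlapped by the other list (vertical axis) in 5 equal classes of each list ordered by −log10 p (horizontal axis, strongest first), with exact 95% binomial intervals. Sharing falls from 80.6% to 19.2% in the Vector list and from 93.4% to 47.0% in the PIM1 list.

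At sites bound in both infections, HDAC2 pileup was lower in PIM1 cells. Over the 5040 shared peaks with a single partner in each list, the summed Vector pileup per background was 1.11 times the PIM1 pileup (1.1 to 1.12), and it was higher in Vector at 66.0% of them. At 1181 peaks with at least 60 fragments in both libraries together the ratio was 1.15 (1.14 to 1.17), and at 146 with at least 100 it was 1.2 (1.17 to 1.24), with Vector higher at 83.6%. Over all these pairs, gene-end peaks (1.12, 1.1 to 1.14) and other peaks (1.11, 1.1 to 1.12) had similar ratios. With at least 60 fragments, the ratio was 1.1797 (1.145 to 1.215) at 225 gene-end peaks and 1.1436 (1.127 to 1.160) at 956 others. Vector was higher at 77.8% of these gene-end peaks and 69.8% of the others. The intervals overlapped, and this difference among strong peaks was not tested. Peaks had to pass the caller in both libraries to enter these sums.

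**Figure D3:**
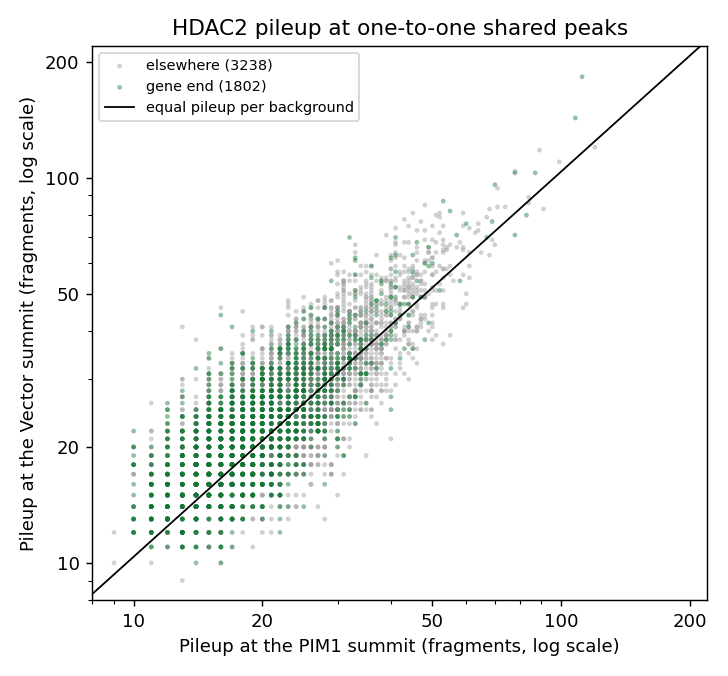
Pileup at the Vector summit against pileup at the PIM1 summit (fragments, log scales) for shared peaks with a single partner, 1802 at gene ends (green) and 3238 elsewhere (grey); the line marks equal pileup per background. Vector lies above the line at 66.0% of the peaks.

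Among shared gene-end peaks with the highest folds, the ratio of Vector to PIM1 pileup ranged from 0.877 to 1.65, with wide counting intervals. TDRD7 had 183 Vector and 112 PIM1 fragments, a ratio of 1.58 (1.24 to 2.01). VIM, the intermediate filament protein vimentin, had 70 and 41 (1.65, 1.1 to 2.48; chromosome 10, 17228243 to 17229076), and CCDC88A, an actin-binding signalling protein, had 87 and 53 (1.58, 1.11 to 2.27; chromosome 2, 55419675 to 55420162). COLEC12, a collectin scavenger receptor, had 82 and 55 (1.44, 1.01 to 2.06). The intervals of the other 6 held 1. Among them were ZEB1 (1.28, 0.987 to 1.65), OVOL1 (71 and 78 fragments, 0.877, 0.627 to 1.23), the YAP partner TEAD1 (70 and 67, 1.01, 0.710 to 1.43) and the AP-1 subunit JUND (60 and 48, 1.2, 0.811 to 1.80). The rest were PKDCC (1.14) and SLC9D1 (1.27).

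Gene-end peaks without an overlapping peak in the other list had lower folds than these. In the Vector list the highest lay at MMAA, a protein of mitochondrial cobalamin metabolism (chromosome 4, 145619037 to 145619482, fold 10.7, 31 fragments), the ETS factor ERF (fold 10.0, 29 fragments), MCRIP1 (fold 8.93), the deubiquitinase USP4 (8.85), the secreted pattern recognition protein PTX3 (8.77), TTLL4 (8.76) and the forkhead factor FOXQ1 (8.67). NLRC5, an activator of MHC class I genes, had a fold of 8.18, followed by PHLDB3 (8.16) and RCAN3 (8.14). In the PIM1 list the highest lay at MAPK8IP2, a scaffold of JNK signalling (chromosome 22, 50600157 to 50600421, fold 9.23, 26 fragments), EDDM3B (9.04), SUSD6 (8.62), DENND4C (8.54) and the serotonin receptor gene HTR5A (7.82). SSU72, an RNA polymerase II phosphatase, followed at 7.67, then the pacemaker channel gene HCN4 (7.52), MISP3 (7.52), YPEL1 (7.18) and SLC10A6 (7.06).

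The introduced gene and the ChIP target were examined first among single genes. At PIM1 (chromosome 6, 37170152 to 37175428), the Vector list held a gene-end peak inside the gene (37170390 to 37170693, fold 3.87, 14 fragments), close to the lower quartile of fold in that list (3.79), and the PIM1 list held none. Neither list held a gene-end peak at HDAC2 (chromosome 6, 113933028 to 113971148). A peak list does not measure the level of the introduced PIM1, so these values do not check the labels.

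Gene ends held 37.6% of Vector peaks on the autosomes and X (36.7 to 38.5) and 36.2% of PIM1 peaks (35.1 to 37.3), against 3.25% after circular shifts in each list. The order of these shares depended on the setting: 32.5% and 28.8% at a −log10 q of at least 5, and 33.1% and 36.2% at equal list length. Gene bodies held 30.0% and 30.3%, and intergenic sequence 32.4% and 33.5%. Gene-end peaks were the weaker ones: they made up 25.1% of the strongest 20% and 46.5% of the weakest 20% of the Vector list, and 22.7% and 48.4% in the PIM1 list. A gene-end peak marked 23.6% of protein-coding genes in Vector and 14.7% in PIM1. For lncRNA genes the shares were 8.88% and 5.63%, for tRNA genes 8.39% (5.95 to 11.4) and 5.13% (3.24 to 7.66), and for pseudogenes 0.756% and 0.408%.

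Of 19974 protein-coding genes, 4720 had a gene-end peak in the Vector list and 2946 in the PIM1 list. Both lists marked 2153 genes, the Vector list alone 2567 and the PIM1 list alone 793, a ratio of 3.24. Thus 45.6% of the Vector genes were also PIM1 genes and 73.1% of the PIM1 genes were also Vector genes. With as many peaks taken from the top of each list by p, the ratio turned to 0.834. That setting removes only the weakest Vector peaks, which lay at gene ends more often than strong ones.

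Wnt pathway genes, intestinal transcription factor and growth signal genes, and immediate early and stress genes stood high among random lists in both infections. Of the 18 lists, 8 in Vector and 5 in PIM1 lay at or above percentile 95. The random lists drew on all protein-coding genes without matching on GC content, so a high rank need not be particular to a pathway. Of 35 Wnt pathway genes, 19 had a gene-end peak in Vector (percentile 100) and 14 in PIM1 (99.99), with 10 in both. NOTUM, a Wnt-inactivating enzyme, had folds of 9.26 and 7.65, and the cyclin gene CCND1 8.37 and 2.91. The CCND1 pileups were 43 and 25 fragments (ratio 1.66, 0.990 to 2.83) over backgrounds of 4.26 and 7.95. SP5 (6.96) and TCF7L1 (5.40) were in the Vector list alone, WNT3 (5.46) and DVL3 (4.83) in the PIM1 list alone. Of 28 intestinal transcription factor and growth signal genes, 15 were marked in Vector (99.95) and 9 in PIM1 (98.99), all 9 in both. TEAD1 had folds of 15.1 and 17.5 and KLF3 of 7.69 and 10.6, while SMAD3 (5.45) and SMAD6 (3.91) had a Vector peak alone. Of 24 immediate early and stress genes, 13 were marked in Vector (99.93) and 9 in PIM1 (99.64), with 6 in both, led by JUND (16.1 and 15.3) and GADD45B (7.37 and 6.49). ATF4 (4.33) and EGR2 (4.17) had a Vector peak alone, KLF6 (5.08) and SESN2 (4.34) a PIM1 peak alone. With lists of equal length the Vector count minus the PIM1 count was −3 for Wnt genes and −4 for immediate early and stress genes.

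Several lists had a lower percentile in PIM1 than in Vector, and these differences were not tested. Random lists also held fewer marked genes in PIM1, so a percentile can fall without a lower count relative to random. Mean random counts in Vector and PIM1 were 5.49 and 3.41 for Notch, 5.44 and 3.41 for junction, and 4.69 and 2.92 for PIM kinase related genes. They were 5.01 and 3.12 for NF-kB and 3.77 and 2.37 for stem cell genes, and the last stayed above percentile 95 in both. Of 23 Notch pathway genes, 12 were marked in Vector (percentile 99.84) and 5 in PIM1 (82.1). The 5 were marked in both, including HES1, a Notch target (folds 9.50 and 4.82; pileups 45 and 40 over backgrounds of 3.84 and 7.50, ratio 1.08, 0.692 to 1.70), and NOTCH1 (6.65 and 4.53); the ligand gene JAG2 (5.83) and SPEN (5.05) had a Vector peak alone. Of 23 junction genes, 11 were marked in Vector (99.4) and 5 in PIM1 (81.5), with CLDN15 (11 and 10.3) and PATJ (3.72 and 5.48; pileups 18 and 19) in both, and MARVELD2 (5.27) and TJP1 (3.92) in Vector. With equal list lengths the difference for junction genes was −1. Of 20 PIM kinase related genes, 9 were marked in Vector (98.2) and 4 in PIM1 (75.6); CXCR4 (6.84 and 3.55, at separate peaks) and PIM3 (4.21 and 3.29) were in both, SOCS1 (6.19) and FOXO3 (5.58) in Vector, JAK2 (4.11) in PIM1. With gene ends of 3 kb this list had 12 and 9 marked genes, with percentiles of 99.85 in Vector and 99.77 in PIM1. Other settings kept a difference: 6 Vector and 0 PIM1 genes at a −log10 q of at least 5, 3 and 0 at the fold limit, and 6 and 4 at equal list length. Of 21 NF-kB and inflammation genes, 10 were marked in Vector (99.1) and 6 in PIM1 (94.6), all 6 in both. IRF1 had folds of 7.03 and 7.30 and NFKB2 of 4.75 and 6.07; NFKB1 (5.67) and RELA (4.45) had a Vector peak alone. Of 16 intestinal stem cell genes, 8 were marked in Vector (98.8) and 5 in PIM1 (95.3), with ASCL2 (10.6 and 11.5) and TNFRSF19 (6.98 and 6.51) in both and BMI1 (4.22) and EPHB2 (4.04) in Vector. At equal list length both infections had 6 NF-kB genes and 5 stem cell genes. The number of Vector genes kept in PIM1 lay between percentiles 24.4 and 82.4 of random draws of as many Vector genes: 5 against 5.49 for Notch (percentile 39.3), 5 against a mean of 5.0 for junctions (50.1), 3 against 4.12 for PIM kinase related genes (24.4), 6 against 4.56 for NF-kB (81.0) and 5 against 3.62 for stem cell genes (82.4).

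Cell cycle genes had about as many marked members in PIM1 as in Vector: 11 of 30 in Vector (94.7) and 12 in PIM1 (99.95). Of the 11 Vector genes 9 were also PIM1 genes, against a mean of 5.03 in random draws of as many Vector genes (percentile 99.0). This was the highest such percentile of the 12 lists with at least 3 Vector genes; the lowest was 1.33, for histone genes, with 0 of 6 kept. CCND1 and the licensing factor gene CDT1 (5.83 and 7.27) were in both, AURKA (3.0) and MCM2 (2.88) in Vector, CCND2 (5.09) and MKI67 (5.09) in PIM1. The order turned at a −log10 q of at least 5, with 7 genes in Vector and 4 in PIM1.

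Replication-dependent histone genes carried few peaks: 6 of 70 in Vector (percentile 0.050), among them H4C16 (4.65) and H2AC15 (3.61), and 0 in PIM1 (0.0050). Ribosomal protein genes had 2 of 30 in each list (0.890 and 10.5), with RPL10A (3.87) and RPL7A (3.29) in Vector and RPL6 (4.57) in PIM1. Against matched random lists the percentiles were 3.08 and 0.0250 for histone genes and 4.63 and 22.8 for ribosomal protein genes. Of 390 olfactory receptor genes 2 were marked in Vector and 1 in PIM1 (0 and 0): OR5H1 in both lists (4.67 and 4.44) and OR5A2 in Vector (6.34).

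Differentiation genes and co-repressor genes lay between percentiles 4.20 and 74.5 with gene ends of 1 kb. Of 23 absorptive enterocyte genes, 6 were marked in Vector (percentile 62.2) and 3 in PIM1 (43.9). The brush border peptidase gene DPP4 had folds of 8.62 and 7.37 and the intestinal homeobox gene CDX1 of 3.56 and 7.57 (pileups 26 and 35, ratio 0.716, 0.414 to 1.22), with EZR (7.01) and HNF4G (5.99) in Vector. Of 23 goblet and secretory genes, KLF4 (5.24 and 4.17) and XBP1 (4.04 and 3.32) were marked in both infections (4.20 and 22.9). Of 26 HDAC co-repressor genes, 6 were marked in Vector (49.5) and 5 in PIM1 (74.5), with ING2 (5.36 and 8.01; pileups 22 and 23) and MTA1 (4.98 and 3.78) in both, RCOR1 (5.48) and MBD3 (3.35) in Vector and MTA3 (3.59) and MTA2 (3.55) in PIM1. With gene ends of 3 kb the percentile rose to 85.1 for goblet and secretory genes in PIM1 (6 genes), 71.1 for enterocyte genes in PIM1 (5 genes) and 79.6 for co-repressor genes in Vector (9 genes).

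Markers of other cell types were marked at 0 to 2 of 12 genes. None of 12 stromal and endothelial genes had a gene-end peak in either list (1.96 and 7.31). Of 12 immune genes, ITGAM was marked in both (4.21 and 4.68) and the monocyte gene CD14 (4.90) in PIM1 (11.6 and 61.0). Of 12 neuronal genes, GRIN1, a glutamate receptor subunit gene, was marked in both (11.3 and 30.3). Its peak (chromosome 9, 137168439 to 137170355 in Vector) was strong. The fold was 14.7 with 62 fragments in Vector and 7.50 with 33 fragments in PIM1, a pileup ratio of 1.81 (1.17 to 2.85). Both summits (137169328 in Vector, 137169329 in PIM1) lay outside the gene, past its higher-coordinate end (137168756). Without strand, whether that end is the promoter was not determined, so the peak need not mark the GRIN1 promoter.

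**Figure D4:**
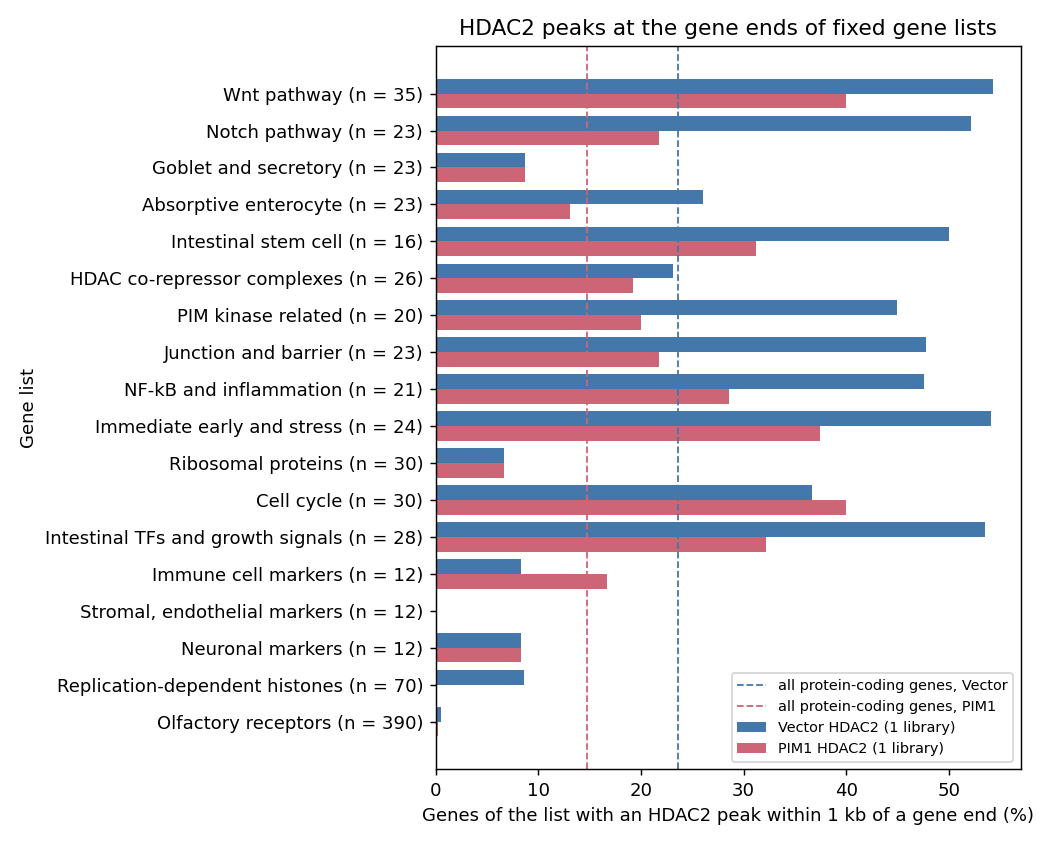
Percent of the genes of each fixed list with an HDAC2 peak within 1 kb of a gene end (horizontal axis) in Vector (blue) and PIM1 (red); dashed lines give all protein-coding genes, 23.6% and 14.7%. Wnt genes reach 54.3% and 40%, and cell cycle genes are 36.7% in Vector and 40% in PIM1.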

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

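Peaks on mitochondrial DNA lay outside the comparisons of places and genes. Each list held 2 of them, with pileups of 1583 and 3398 fragments in Vector and 1584 and 3080 in PIM1, far above the 9 fragments of the smallest peak in each list. Their folds were only 1.19 and 1.37 in Vector and 1.41 and 1.31 in PIM1, over backgrounds of 1331, 2482, 1127 and 2349 fragments. The rule that picked them asks for signal left out of such comparisons. The mitochondrial peaks did count in the peak totals, the overlap of the lists, and the fold and width of shared against unshared peaks. No explanation was tested.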

How the results depend on the processing

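The repeat, GC, 5-prime end and motif alternatives were not run for lack of sequence and strand, and a pseudocount of 0 gave no values. No paired analysis was possible because each group held 1 library. The excess of Vector peaks held in every setting that could change it: at a fold limit, on autosomes and X, with merging and with a common p minimum (the last added after seeing the data) the ratio was 1.55 to 1.58, and at a −log10 q of at least 5 the ratio was 1.70.

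At that q limit 41.4% of Vector and 70.6% of PIM1 peaks were shared, 32.5% and 28.8% lay at gene ends, and 888 genes were marked in both, 1605 in Vector alone and 416 in PIM1 alone (ratio 3.86). At a fold of at least the Vector median the shares were 38.0% and 59.1% shared and 33.3% and 31.3% at gene ends, with 776 genes in both and 1394 in Vector alone (ratio 2.51). With the strongest peaks at equal list length, 55.5% of Vector and 56.2% of PIM1 peaks were shared, 33.1% and 36.2% lay at gene ends, and 1138 genes were marked in Vector alone and 1364 in PIM1 alone, which turned the ratio to 0.834. That setting takes its lower rank limit from list length, and 5 gene lists then had more Vector members, against 12. It also turned the Vector minus PIM1 difference of Wnt (−3), co-repressor (−1), junction (−1) and immediate early genes (−4). The fold limit turned junction (−1) and cell cycle genes (1), and the q limit cell cycle genes (3). The cause was not tested beyond list length.

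Reciprocal overlap of 50% gave 34.1% and 53.8% shared, and a distance of 1 kb 47.5% and 73.3%. The share of pairs with the higher fold in the shared peak became 66.8% for PIM1 with reciprocal overlap, and 66.0% for Vector and 62.9% for PIM1 with 1 kb. For width it became 61.9% (Vector) and 65.4% (PIM1) with reciprocal overlap and 67.2% (Vector) with 1 kb. Gene ends of 3 kb held 44.3% of Vector and 43.3% of PIM1 peaks, and summits inside 1 kb 35.4% and 34.4%. The weakest 20% of each list had a median pileup of 14 fragments, and the pileup of the other library at unshared sites was not measured. Of 108 list differences recomputed, 68 kept their sign, 9 fell to 0 (among them Wnt and junction genes at the q limit and immediate early genes at the fold limit), 7 turned, 14 stayed at 0 and 10 left 0. Of 36 percentiles, 0 crossed 50 with matched random lists (chosen after seeing the data) and 3 with 3 kb ends (goblet 85.1 and enterocyte 71.1 in PIM1, co-repressor 79.6 in Vector). PIM kinase related genes in PIM1 rose to 99.77 with 3 kb ends. With matched lists 1 percentile left the top 5% (stem cell genes in PIM1, 93.4) and 2 entered it (NF-kB genes in PIM1, 97.2, and cell cycle genes in Vector, 95.8).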

Other observations

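Some genes had many HDAC2 peaks around them, counted as summits nearest to an end of that gene. This count was chosen after the data were seen. It had no limit on distance, so a gene far from its neighbours can collect more peaks. Nor did it allow for the uneven number of peaks per gene across chromosomes. Of 6965 protein-coding genes with a nearest Vector peak, 15 had at least 12. The growth factor gene BMP7 led with 19 Vector and 17 PIM1 peaks, followed by ZNF703 (18 and 13), the homeobox gene MSX2 (16 and 10), MYC (15 and 11), TBX3 (15 and 13), GATA3 (15 and 7) and GINS2 (15 and 11). Around HAS2, a hyaluronan synthase gene, the numbers were 14 and 4, and around KLF6 12 and 5. The difference of such single loci from the ratio of all peaks was not tested. The Vector list also held a peak on chromosome 16 (46390589 to 46390850) with 640 fragments over a background of 239, with no overlapping PIM1 peak. Its fold was only 2.68, and its background lay far above the list median of 3.47. Other Vector peaks with a background over 20 lay on chromosome 1 (from 125180093 and from 143246875) and on chromosome 21 (from 8219777). Repeats were not excluded, so the chromosome 16 peak cannot be read as a site particular to Vector.

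Tests chosen after the result was seen were those of fragment number, of preparation, of strong peak number and of threshold crossing. The others were fixed before their values. Reading the background test, the threshold test and the count at the PIM1 p minimum as undecided was adopted after their values were seen. For the first pattern, the shorter PIM1 list, a lack of ChIP fragments is argued against by a Vector to PIM1 fragment ratio of 1.00. One common factor of lower enrichment is a candidate explanation for the strong shared peaks. At 1181 of them the spread of the PIM1 share was 0.95 times binomial, inside the simulated range of 0.927 to 1.07. The simulation drew plain binomial counts, whereas the data were pileups at each library's own summit, from pairs called in both lists. Such selection can narrow the spread, so differences between sites may be hidden. Over all 5040 pairs the ratio at gene ends over elsewhere was 1.01 (0.995 to 1.02). That comparison was not made for the 1181 strong peaks alone. Among those, the Vector to PIM1 ratio was 1.1797 (1.145 to 1.215) at gene ends and 1.1436 (1.127 to 1.160) elsewhere. Equality over all pairs therefore does not show equality at strong peaks. Yet the Vector to PIM1 pileup ratio rose with strength. It was 1.09 (1.08 to 1.1) under 60 fragments in both libraries together and 1.2 (1.17 to 1.24) at 100 or more. Pileup includes background and weak peaks had to pass in both lists, so whether this rise departs from 1 factor was not tested. The strong shared peaks passed in both lists, although 2.87% of 628 Vector peaks with at least 40 fragments had no PIM1 peak. Dividing the Vector signal by the pooled net ratio of 1.17 left 1.42 times the PIM1 list at its p minimum, past the 1.1 times allowed. That count used the p at the summit alone. A limit on width may also remove peaks, but this was not tested. The narrowest peaks, 234 bp in Vector and 226 bp in PIM1, matched the fragment lengths only because those were searched close to these widths. By the limit set beforehand, the count went against that factor as the whole cause of the shorter list. Because it used the summit p alone and no width limit was tested, this reading was left undecided. At −log10 p of at least 15 the division left 0.906 times the PIM1 number (0.835 to 0.983), at the edge of what was allowed. Giving shared peaks the PIM1 background lost 0.694% of Vector calls, but only 42.5% of Vector peaks could be tested. Each of those had a PIM1 call over that same background, so a small loss was likely from the start. Sites where a high PIM1 background removed the call could not enter, so this test cannot decide. A difference between 1 preparation per infection and the infection itself cannot be told apart.

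The second pattern is the 2305 PIM1 peaks with no Vector peak. Of the strongest 20% of the PIM1 list 6.58% had no Vector peak, against 53.0% of the weakest; chance crossing of the threshold and a true difference at weak sites would both give this gradient and cannot be told apart without a replicate. The third pattern is the uneven number of peaks per gene across chromosomes. Extra chromosome copies are a candidate explanation that these values cannot decide. Over 23 chromosomes the median background at the called peaks and Vector peaks per 1000 genes had a Spearman rho of 0.795 (permutation p = 1e-05, the smallest possible, adjusted 3e-05). The Pearson r was 0.767 (permutation p = 2e-05, adjusted 3e-05). PIM1 gave 0.786 and 0.786. Without chromosomes 20 and 13 the Vector r was 0.707. Of 3 relations computed, that of background with the Vector to PIM1 ratio was negative (rho −0.583, permutation p = 0.00407, adjusted 0.00407; r −0.523, p = 0.0117). Chromosomes of 1 library are not replicates, and copy number itself was not measured. Background was taken at the called peaks, not over whole chromosomes, so both values come from the same peaks. Division by genes also shapes the pattern: chromosomes 13 and 19 held 398 and 408 Vector peaks but 338 and 1451 protein-coding genes.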
